A study of Candida albicans with 12 samples.

How the data were processed

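Polyadenylated RNA of Candida albicans strain SC5314, a diploid yeast that grows as budding yeast-form cells or as filamentous hyphae, was measured in 12 libraries that formed 4 groups of 3. Yeast-form and hyphal cultures had each received the peptide PYY1-36 at 30 µM or saline, and were harvested after 4 h, per the labels. The labels number the libraries 1 to 3 in each group but do not say that they came from separate cultures, so every p-value measures the spread between these samples, which may be technical. RNA was extracted with a column kit and made into stranded libraries by oligo-dT selection, per the labels' protocols.

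The authors deposited a single table of whole-number read counts per gene, not normalised, with a column for each library. Alignment and counting were done with STAR and featureCounts after FastQC, per the submitters' processing notes, which give no versions, and the strand setting of the counting is not given in the sources used here. Antisense and overlapping genes were therefore treated as uncertain, as were near-identical paralogs such as the ALS adhesins, the SAP4 to SAP6 proteases and the histone genes, whose shared reads the counting could have split or left out. The table also gives the start, end and strand of each gene. All 6263 gene identifiers matched the RefSeq gene table of assembly ASM18296v3, and all 6263 had identical start and end positions there, so coordinates are given on that assembly, counted from 1. Of these genes, 2962 had a symbol of their own. The others entered every test and count but are not named. The table held 6030 protein-coding genes, 126 tRNA, 75 small nucleolar RNA, 5 small nuclear RNA and 4 ribosomal RNA genes, 18 pseudogenes, 3 other non-coding RNA genes and 2 miscellaneous RNA genes. Values of ribosomal and other RNAs that lack a poly(A) tail depend on how they passed the oligo-dT selection, and are uncertain for that reason. No gene of the mitochondrial genome was in the table. GC content was not analysed, since no genome sequence was used here.

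The total count per library ranged from 60496545 to 64386087, so depth differed little. At these totals 3 counts correspond to 0.0466 to 0.0496 CPM (counts scaled to a common library total), which covers counting error only. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 6103 genes and removed 160. Of the 6263 genes, 33 had no count in any library.

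The main test was edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, robust; edgeR 4.0.16 in R 4.3.3) with TMM scaling on all 12 libraries, a single term for group and 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 6103 genes within each contrast, and a gene was called at an adjusted p under 0.05. The 4 contrasts were PYY1-36 minus saline in yeast-form cultures, PYY1-36 minus saline in hyphal cultures, the difference of these 2 responses (hyphal minus yeast-form), and hyphal minus yeast-form saline controls. Standard errors (SE) of log2 fold changes were the absolute fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, given as mean ± SD with n = 3.

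Before the data were examined, 31 gene lists were fixed from textbook knowledge. They covered growth form, virulence, the cell envelope, stress, nutrient uptake, metabolism, ribosomes, the cell cycle and drug efflux. A list of transcripts of the mitochondrial genome had no gene in the table, so 30 lists were tested. A list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists within each contrast. It was tested again with an estimated correlation and with fry, which tests whether the members move on balance in a single direction without comparing them with other genes. The rule for named genes was also fixed then. Each contrast names the 10 largest increases and the 10 largest decreases among called genes with a symbol and a mean of at least 10 CPM in some compared group, for which the groups did not overlap (not required for the difference of responses). It also names up to 4 members of each list with the smallest adjusted p, members of the hypha-associated and yeast-form lists, and the form markers YWP1, HWP1, ECE1 and ALS3. No statement about a list was made from symbols that the table lacks.

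The script was tested on simulated counts for 6103 genes, drawn with the real means and library sizes and with the dispersion of each form's own 6 libraries, in 5 simulated sets with 200 changed genes each. For the yeast-form comparison the fit of all 12 libraries recovered 47.6% of genes changed 1.25-fold, 84.8% at 1.5-fold, 94% at 2-fold and 97.6% at 4-fold, and 25.3% of its calls were false. A fit of the 6 yeast-form libraries alone recovered 29.2%, 76.8%, 94% and 95.6% at those sizes, with 4.89% false calls. For the hyphal comparison the fit of all 12 libraries recovered 44.8%, 86.8%, 95.2% and 98.8%, with 0.732% false calls, and the fit of the 6 hyphal libraries alone recovered 83.6%, 92.4%, 97.6% and 99.2%, with 6.05% false calls. The difference follows the spread of the groups. The biological coefficient of variation was 7.43% in yeast-form controls, 13.4% in PYY1-36-treated yeast-form cultures, 5.34% in hyphal controls and 5.87% in PYY1-36-treated hyphae, against 8.25% in the shared fit.

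The alternatives were RLE scaling, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 10 CPM, the replicate number as a block, leaving out each library in turn, fitting only the groups compared, and an added threshold of 1 on the absolute log2 fold change. Leaving out the non-coding genes before scaling, and the difference of the responses taken from separate fits by a normal approximation, were added after the data had been seen. Replicates were compared before averaging, and the mean chi-square per gene between replicates of a group ranged from 13.5 to 147, where counting error alone would give about 1, so no pair looked like copies of a single library.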

Results

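RNA-seq counts were collected from yeast-form and hyphal cultures of Candida albicans SC5314 that had been exposed for 4 h to 30 µM of PYY1-36, the full-length gut hormone peptide YY, or to saline. Each of the 4 groups held 3 libraries, and the total count per library lay between 60496545 and 64386087. The first principal component of log2 CPM carried 90.1% of the variance and separated the growth forms. On the second, which carried 2.99%, treated yeast-form replicate 1 stood apart from replicates 2 and 3 of its group, at 21.9 against -0.142 and 2.66. Ribosomal RNA took 2.53% ± 0.246 of the counts in yeast-form controls and 4.47% ± 1.29 in PYY1-36-treated yeast-form cultures (SD, n = 3 each). In hyphae it took 0.843% ± 0.246 with saline and 0.605% ± 0.085 with PYY1-36.

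The saline controls of the growth forms were compared first, which also checks the labels. The labels give neither medium nor temperature, so growth form cannot be told apart from culture conditions. That limit also applies where the responses of the forms are compared. Hyphal controls carried ECE1, the candidalysin precursor gene (CAALFM_C403470CA, chromosome 4, 726514 to 727329 on assembly ASM18296v3), at 3860 ± 162 CPM, against 0.561 ± 0.221 in yeast-form controls. The hyphal wall protein gene HWP1 (chromosome 4, 762835 to 764739) was higher by a log2 fold change of 7.70 ± 0.15 (SE), and the adhesin and invasin gene ALS3 by 5.47 ± 0.15. The superoxide dismutase gene SOD5 reached 1310 ± 185 CPM in hyphae and the protease gene SAP5 396 ± 60.5. The phosphate transporter gene PHO89 reached 764 ± 22.8 CPM, the zinc transporter gene ZRT1 440 ± 78 and the zinc-scavenging antigen gene PRA1 810 ± 177. YWP1, the yeast-form wall protein gene (chromosome 2, 1746839 to 1748440), went the other way, from 486 ± 60.3 CPM in yeast form to 1.07 ± 0.0393 in hyphae. So did the glucose transporter family gene HGT17, the inositol-1-phosphate synthase gene INO1 and the small heat shock protein gene HSP21. ASR2, HSP30, PBR1, LDG3, FMP45 and RBR1 were lower as well, and these 9 genes had log2 fold changes from -9.53 for HGT17 to -5.91 for ASR2. The ferric reductase family genes CFL2 and CFL11 and the gene FAV1 were higher in hyphae, by 7.33, 5.72 and 8.19, from levels near the floor in yeast-form controls, where FAV1 had 0, 2 and 11 counts.

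**Figure D1:**
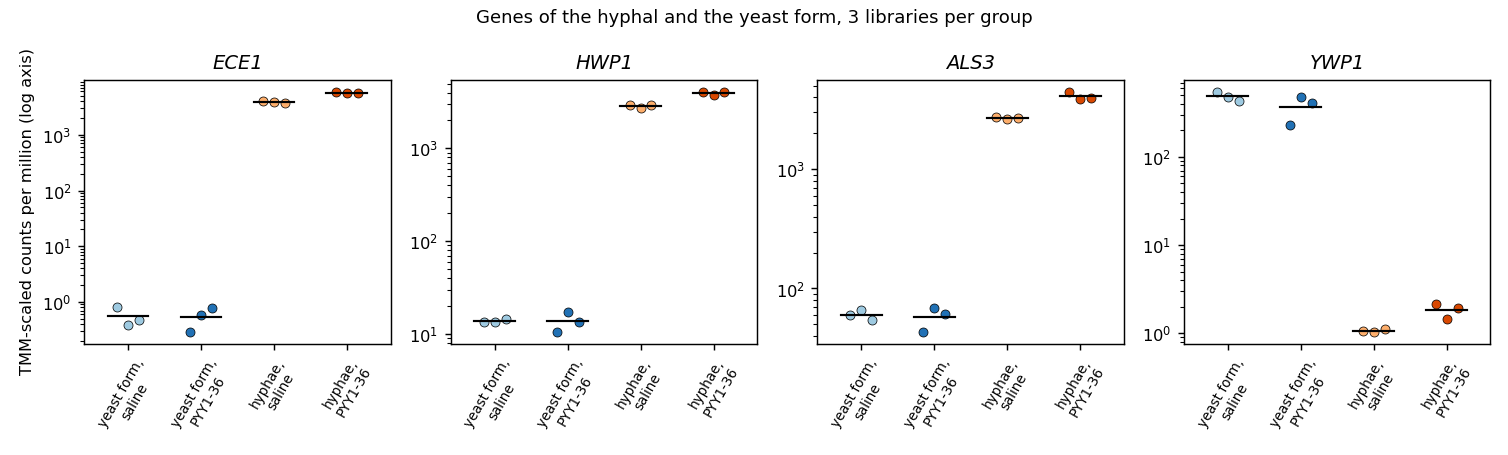
TMM-scaled CPM on a log axis of the hyphal genes ECE1, HWP1 and ALS3 and the yeast-form gene YWP1, with a point per library and a bar at the mean of each group of 3. The hyphal libraries lie far above the yeast-form libraries for the first 3 genes and far below them for YWP1.

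Whole groups of genes differed between the controls. Of 17 hypha-associated genes, 16 were higher in hyphae (16 adjusted over the list alone; camera adjusted p = 4.15e-12, and adjusted p = 0.0902 with an estimated correlation). Only ALS1 among them did not pass, at -0.02 ± 0.11, and under scaling by library size alone it was called higher at 0.62. Among 10 yeast-form genes 8 were lower and 2, RHD1 and RHD2, were higher (8 and 2 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.178 with an estimated correlation). All 63 tested ribosome biogenesis genes were higher in hyphae (63 adjusted over the list alone), with NOC2 at 3.73 ± 0.07 and NOG1 at 3.07 ± 0.08. Camera gave the list an adjusted p = 1.3e-23, and adjusted p = 0.275 with an estimated correlation. All 17 genes of glycolysis and fermentation were lower (17 adjusted over the list alone), among them the glycolysis regulator TYE7 at -4.40 ± 0.09 and hexokinase HXK2 at -3.36 ± 0.08. Camera gave the list an adjusted p = 2.17e-12, and adjusted p = 0.178 with an estimated correlation. Of 13 hexose transport genes 11 were lower and 2 higher, adjusted over the list alone as well (adjusted p = 1.74e-08, and adjusted p = 0.0902 with an estimated correlation). Of 25 heat shock and chaperone genes 21 were lower and 3 higher, adjusted over the list alone as well (adjusted p = 2.29e-08, and adjusted p = 0.192 with an estimated correlation). Iron uptake genes were higher for 20 of 29 and lower for 6, adjusted over the list alone as well, with the multicopper oxidase gene FET34 at 4.59 ± 0.11 and FET99 at -5.40 ± 0.14. Camera gave the list an adjusted p = 0.00027, and adjusted p = 0.178 with an estimated correlation.

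Further lists passed between the controls. Ribosomal protein genes were higher for 65 of 72 and lower for 2 (66 and 2 adjusted over the list alone; adjusted p = 0.00184, and adjusted p = 0.714 with an estimated correlation). Sulfur assimilation genes were higher for 15 of 20 and lower for 4, adjusted over the list alone as well (adjusted p = 0.0105, and adjusted p = 0.192 with an estimated correlation). Genes of the glyoxylate cycle, gluconeogenesis and fatty acid oxidation were lower for 20 of 29 and higher for 7, adjusted over the list alone as well (adjusted p = 0.000295, and adjusted p = 0.275 with an estimated correlation). Trehalose and glycogen genes were lower for 8 of 11 and higher for 2, adjusted over the list alone as well (adjusted p = 0.00509, and adjusted p = 0.462 with an estimated correlation). Genes of peptide and nitrogen use were lower for 22 of 38 and higher for 12, adjusted over the list alone as well (adjusted p = 0.011, and adjusted p = 0.423 with an estimated correlation). Filamentation repressors were lower for 4 of 6 and higher for 2, adjusted over the list alone as well (adjusted p = 0.0268, and adjusted p = 0.349 with an estimated correlation). Proteasome genes were lower for 21 of 26, adjusted over the list alone as well (adjusted p = 0.0354, and adjusted p = 0.64 with an estimated correlation), but their median of -0.46 became 0.18 under library size alone (adjusted p = 0.216), and the stricter filter gave 0.0705. Tricarboxylic acid cycle genes were lower for 11 of 20 and higher for 7, adjusted over the list alone as well (adjusted p = 0.0424, and adjusted p = 0.462 with an estimated correlation), with a median of -0.56 that became 0.09 under library size alone (adjusted p = 0.149). That call also ended with the stricter filter (0.0774), with the controls fitted alone (0.053), and without yeast-form control replicate 3 (0.0501), treated yeast-form replicate 1 (0.0608) or hyphal control replicate 2 (0.0529). Adhesins, secreted aspartyl proteases, filamentation activators, zinc and copper uptake, osmotic stress, protein folding in the endoplasmic reticulum, sphingolipid and fatty acid synthesis, and the lists of cell wall synthesis and integrity passed by camera in none of the contrasts, including those of PYY1-36, with a smallest adjusted p of 0.06. By fry, which does not compare the members with other genes, all 30 tested lists passed between the controls.

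By edgeR's quasi-likelihood test, 5158 of 6103 genes differed between the controls, 2615 higher and 2543 lower in hyphae, and 2337 of them by at least 1 on the log2 scale. With scaling by library size alone the split was 4029 higher and 1314 lower, because the median of all genes moved from 0.02 to 0.66, so directions of moderate differences are relative to the TMM scaling.

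PYY1-36 was then compared with saline in yeast-form cultures. FMO1 fell from 14.1 ± 0.909 to 1.64 ± 0.518 CPM, a log2 fold change of -3.11 ± 0.19 (adjusted p = 2.02e-07; chromosome 2, 402391 to 404049). INO1, which encodes the enzyme that commits glucose-6-phosphate to inositol synthesis, fell from 879 ± 74.2 to 242 ± 16.1 CPM (-1.86 ± 0.08, adjusted p = 1.43e-08; chromosome R, 2155482 to 2157044). The hydroxypropionate dehydrogenase gene HPD1 fell by 2.92 ± 0.23 on the log2 scale, the glycerophosphoinositol transporter gene GIT1 by 1.88 ± 0.16 and the acid phosphatase gene PHO112 by 1.75 ± 0.19. OPT7, an oligopeptide transporter gene, fell by 1.75 ± 0.11, the formate dehydrogenase gene FDH1 by 1.68 ± 0.11, the ferric reductase gene FRE7 by 1.58 ± 0.10 and the sulfate assimilation gene MET14 by 1.52 ± 0.11. A second acid phosphatase gene, PHO100, fell by 2.02 ± 0.41, with an adjusted p of 0.0732 when the yeast-form libraries were fitted alone (0.000168 to 0.0732 over the alternatives).

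Among the 10 genes with a symbol, at least 10 CPM and the largest increases in yeast-form cultures, 6 were ribosomal and other non-coding RNAs, whose level in libraries selected by oligo-dT is uncertain. SCR1, the RNA of the signal recognition particle, rose from 169 ± 14.6 to 365 ± 72.6 CPM, and RPR1, the RNA of ribonuclease P, from 112 ± 7.28 to 208 ± 51.1. Ribosomal RNA genes were higher by 1.92 ± 0.46 for RDN5, 1.35 ± 0.37 for RDN58, 0.93 ± 0.25 for RDN18 and 0.89 ± 0.21 for RDN25. Fitted on the yeast-form libraries alone, RDN5 and RDN58 had adjusted p of 0.111 and 0.141, and by limma-voom of 0.0808 and 0.0538. Their lowest over the alternatives were 0.000245 and 0.000877. RDN18 lost its call without yeast-form control replicate 3 (0.0548) and without treated yeast-form replicates 1 (0.0686) or 2 (0.0662), and RDN58 without yeast-form control replicates 1 (0.0571) or 3 (0.0627). Among protein-coding genes the retrotransposon gene POL93 rose by 0.89 ± 0.12, NBP2 by 0.72 ± 0.08, the subtelomeric gene TLO4 by 0.70 ± 0.11 and the peroxisomal ubiquitin-conjugating enzyme gene PEX4 by 0.69 ± 0.09.

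**Figure D2:**
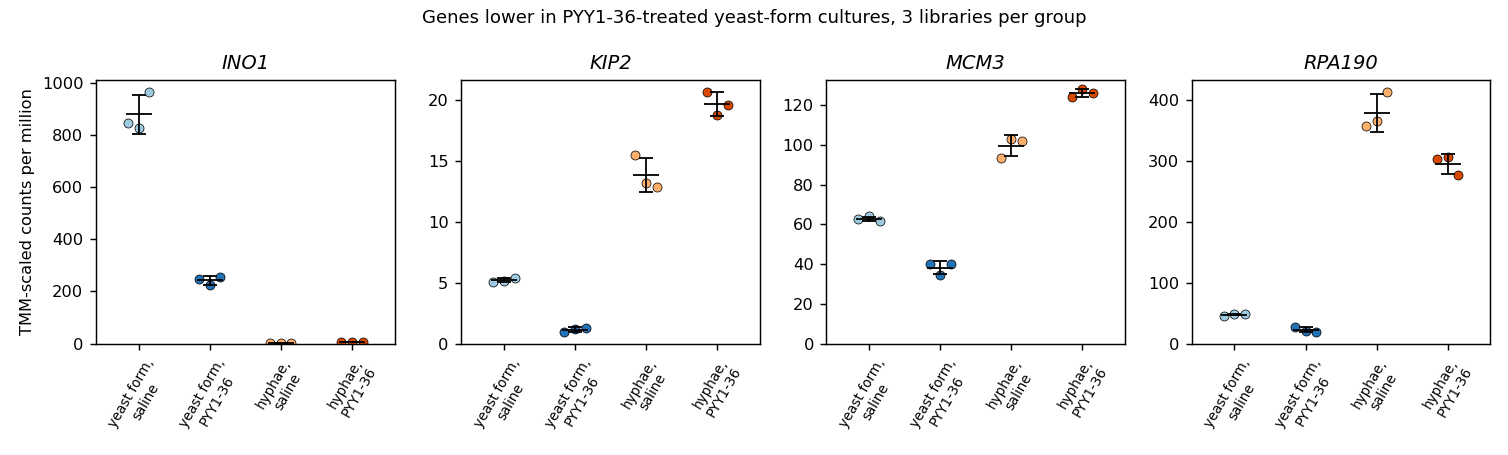
TMM-scaled CPM of INO1, KIP2, MCM3 and RPA190 in all 4 groups, with a point per library and bars for the mean and SD of 3. In yeast-form cultures each gene is lower with PYY1-36 than with saline, as for INO1 at 242 against 879 CPM.

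The fixed lists grouped these changes. Among 10 yeast-form genes 6 fell and none rose (7 adjusted over the list alone; camera adjusted p = 1.11e-05, and adjusted p = 0.102 with an estimated correlation). The 6 included RHD2 at -1.15 ± 0.11, the cell wall gene SCW11 at -0.90 ± 0.11 and the filamentation repressor NRG1 at -0.47 ± 0.08. RHD2 was higher in hyphal than in yeast-form controls, by 1.33. YWP1 stood at -0.39 ± 0.19 with an adjusted p of 0.157. Of 20 sulfur assimilation genes 10 fell and 1 rose, adjusted over the list alone as well, including MET15 at -0.80 ± 0.08 and MET3 at -0.59 ± 0.06. Camera gave the list an adjusted p = 0.000201, and adjusted p = 0.102 with an estimated correlation. Amino acid synthesis genes fell for 19 of 50 (24 adjusted over the list alone), with TRP3 at -0.63 ± 0.08 and LYS4 at -0.49 ± 0.06. Camera gave the list an adjusted p = 1.59e-05, and adjusted p = 0.333 with an estimated correlation. Of 20 tricarboxylic acid cycle genes 9 fell (10 adjusted over the list alone), with IDH2 at -0.53 ± 0.05 and FUM12 at -0.42 ± 0.06. For the list, camera gave adjusted p = 0.000201, and adjusted p = 0.333 with an estimated correlation. Among 31 genes of electron transport and ATP synthase 5 fell (5 adjusted over the list alone), with the ATP synthase subunit genes ATP2 at -0.50 ± 0.06 and ATP1 at -0.50 ± 0.08. For the list, camera gave adjusted p = 0.00757, and adjusted p = 0.97 with an estimated correlation. That call ended without yeast-form control replicate 3 (adjusted p = 0.111) and without treated yeast-form replicate 2 (0.114), and fry gave 0.0979. Iron uptake genes fell for 7 of 29 and rose for 2 (9 and 3 adjusted over the list alone), with FRE30 at -1.40 ± 0.17 and FET99 at -0.68 ± 0.11. For the list, camera gave adjusted p = 0.0235, and adjusted p = 0.45 with an estimated correlation. Without treated yeast-form replicate 3 their adjusted p was 0.0714.

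Of 38 cell cycle and DNA replication genes 12 fell and 4 rose (17 and 7 adjusted over the list alone), with the replicative helicase genes MCM3 at -0.72 ± 0.07 and MCM6 at -0.65 ± 0.09 and the polo kinase gene CDC5 at -0.76 ± 0.12. For the list, camera gave adjusted p = 0.0108, and adjusted p = 0.858 with an estimated correlation. This call ended without yeast-form control replicate 3 (0.0766) and without treated yeast-form replicate 1 (0.086). Ribosomal protein genes fell for 21 of 72 and rose for 1 (24 and 1 adjusted over the list alone), with RPS20 at -0.45 ± 0.07. For the list, camera gave adjusted p = 1.11e-05, and adjusted p = 0.981 with an estimated correlation. Ribosome biogenesis genes fell for 15 of 63 and rose for 2, adjusted over the list alone as well, with the RNA polymerase I subunit gene RPA190 at -1.06 ± 0.10 and NOC2 at -0.60 ± 0.07. The list had adjusted p = 0.0348, and adjusted p = 0.981 with an estimated correlation. That adjusted p was 0.0978 without yeast-form control replicate 1, 0.1 without control replicate 2, 0.715 without treated replicate 2 and 0.227 without treated replicate 3, and 0.0703 in the fit of the yeast-form libraries alone. By fry the adjusted p was 0.138 for ribosomal protein genes and 0.417 for ribosome biogenesis genes. Genes of the glyoxylate cycle, gluconeogenesis and fatty acid oxidation rose for 14 of 29 and fell for 4, adjusted over the list alone as well (adjusted p = 0.0178, and adjusted p = 0.858 with an estimated correlation). The 14 included the peroxisomal genes PEX4 and PEX13 (0.31 ± 0.05), whereas the gluconeogenic gene PCK1 fell by 0.65 ± 0.09. Without treated yeast-form replicates 1 or 3 the adjusted p of this list was 0.0577 or 0.057. Of 17 hypha-associated genes, IHD1 and PHR1 rose by 0.33 ± 0.07 and 0.30 ± 0.07 and the transcription factor gene UME6 fell by 0.54 ± 0.19 (2 higher and none lower adjusted over the list alone). In the fit of the yeast-form libraries alone PHR1 had an adjusted p of 0.0621 and UME6 of 0.213. The call of UME6 also ended when any single library except treated yeast-form replicate 3 was left out, with adjusted p from 0.0583 (without hyphal control replicate 1) to 0.124 (without yeast-form control replicate 3). The list did not pass (adjusted p = 0.961), with ECE1 at -0.04 ± 0.31, HWP1 at 0.00 ± 0.13 and ALS3 at -0.07 ± 0.13.

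Of 6103 genes, 1549 were called in yeast-form cultures, 787 higher and 762 lower, and 95 of them by at least 1 on the log2 scale (16 higher and 79 lower). The PYY1-36-treated yeast-form libraries varied more than the other groups, and a fit of the yeast-form libraries alone called 658 genes (264 higher and 394 lower), 655 of them among the 1549. Simulated counts took their dispersion from the treated and control yeast-form libraries together, and changed 200 of 6103 genes in each set. The share of false calls depends on how many genes change, so the following shares cannot be carried over to the 1549. In those counts 25.3% of the calls of the shared fit were false, against 4.89% in the fit of the yeast-form libraries alone. Of the 20 genes named by size of change the latter fit called 17, and its falls numbered 4 in the yeast-form list, 8 in sulfur assimilation, 13 in amino acid synthesis, 7 in the tricarboxylic acid cycle, 9 in the cell cycle, 8 among ribosomal proteins, 10 in ribosome biogenesis, 5 in iron uptake and 3 in electron transport and ATP synthase. In the list of the glyoxylate cycle, gluconeogenesis and fatty acid oxidation it called 8 higher and 3 lower. Scaling by library size alone gave 360 higher and 1139 lower genes.

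PYY1-36 was compared with saline in hyphal cultures next. UCF1 rose from 152 ± 7.18 to 1000 ± 83.7 CPM, a log2 fold change of 2.71 ± 0.07 (adjusted p = 1.65e-11; chromosome 2, 1675845 to 1676450). The glucose transporter genes HGT7 (chromosome 2, 164439 to 166079) and HGT6 rose by 1.69 ± 0.07 and 1.57 ± 0.09, and HXK2 (chromosome R, 995376 to 996830) rose from 886 ± 13.3 to 2830 ± 204 CPM. The heme synthesis gene HEM13 rose by 1.56 ± 0.08, the heme-binding surface protein gene PGA10 by 1.56 ± 0.09, the malic enzyme gene MAE1 by 1.34 ± 0.07 and the fumarate reductase gene OSM1 by 1.21 ± 0.07. Transporter genes of drug efflux families went both ways. CDR4 and QDR1 rose by 1.59 ± 0.14 and 1.48 ± 0.08, whereas MDR1 fell from 817 ± 81.5 to 225 ± 41.2 CPM (-1.86 ± 0.30, adjusted p = 0.000526; chromosome 6, 666383 to 668077) and the polyamine transporter family gene TPO3 fell by 1.52 ± 0.19. Other decreases were FDH1 at -1.62 ± 0.11 and the aldo-keto reductase family gene IFD6 at -1.38 ± 0.14. The NADPH oxidoreductase genes OYE32 and EBP1 fell by 1.23 ± 0.17 and 1.15 ± 0.10, and the methylglyoxal reductase gene GRP2 by 1.05 ± 0.09. The superoxide dismutase gene SOD3 fell by 1.17 ± 0.17, the protease gene SAP6 by 1.23 ± 0.27 and the mitochondrial carrier gene OAC1 by 1.03 ± 0.28.

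**Figure D3:**
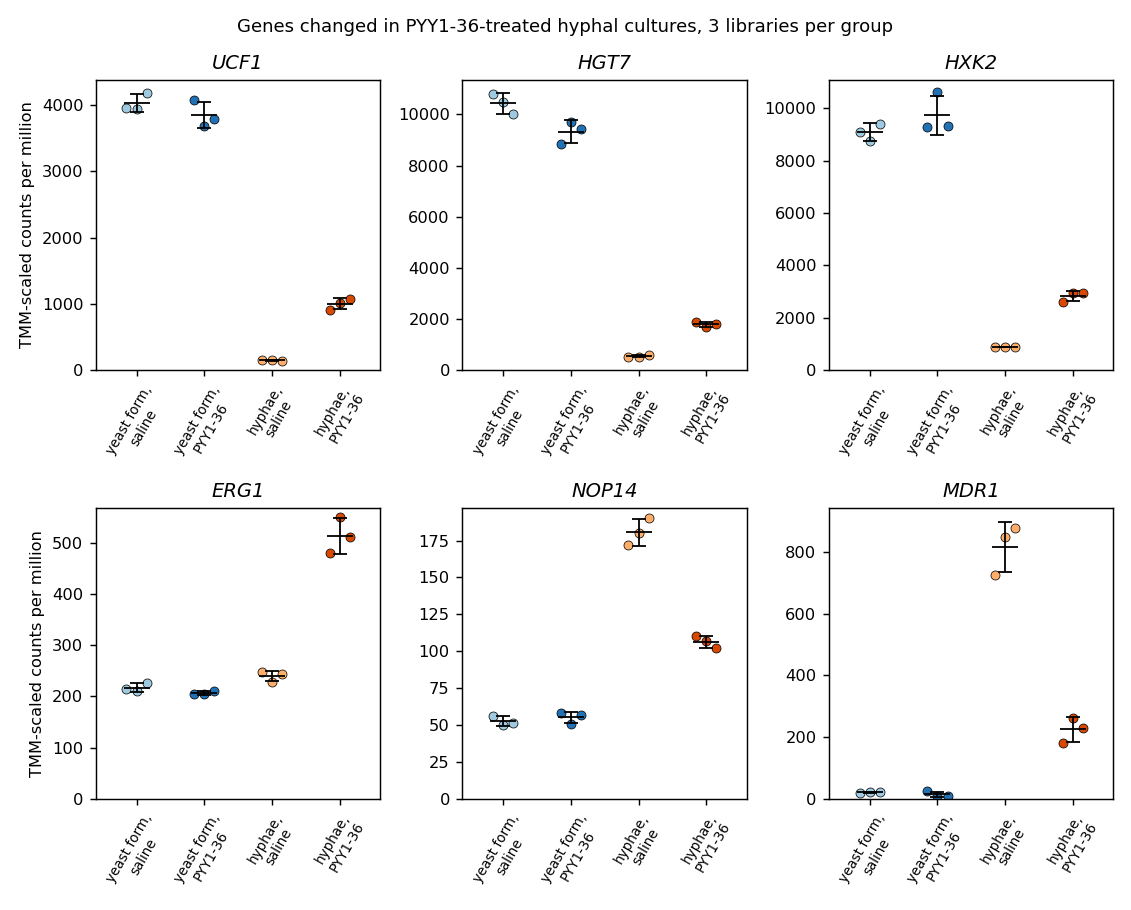
TMM-scaled CPM of UCF1, HGT7, HXK2, ERG1, NOP14 and MDR1 in all 4 groups, with a point per library and bars for the mean and SD of 3. In hyphal cultures the first 4 genes are higher with PYY1-36 than with saline and the last 2 are lower, and UCF1, HGT7 and HXK2 stay below both yeast-form groups.

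All 17 genes of glycolysis and fermentation rose (17 adjusted over the list alone), with PFK2 at 0.91 ± 0.07, FBA1 at 0.95 ± 0.07 and GLK4 at 0.93 ± 0.06 beside HXK2 (adjusted p = 8.88e-25, and adjusted p = 0.0484 with an estimated correlation). Hexose transport genes rose for 10 of 13 and fell for 1 (11 and 1 adjusted over the list alone; adjusted p = 2.89e-09, and adjusted p = 0.0484 with an estimated correlation). Those were the only 2 of the 30 lists to pass in this comparison with an estimated correlation. Of 24 genes of ergosterol and mevalonate synthesis 17 rose and 1 fell (18 and 1 adjusted over the list alone), with squalene epoxidase ERG1 at 1.10 ± 0.06, lanosterol demethylase ERG11, the target of azole drugs, at 0.83 ± 0.06, and ERG3 at 0.77 ± 0.09. The list had adjusted p = 5.35e-09, and adjusted p = 0.114 with an estimated correlation. Trehalose and glycogen genes rose for 8 of 11 (10 adjusted over the list alone), including TPS3 at 0.58 ± 0.06 and TPS1 at 0.53 ± 0.06. The list had adjusted p = 8.24e-05, and adjusted p = 0.46 with an estimated correlation. Cell cycle and DNA replication genes rose for 17 of 38 and fell for 3 (17 and 4 adjusted over the list alone), with the ribonucleotide reductase genes RNR22, from 36.4 ± 1.11 to 72.8 ± 4.16 CPM, and RNR1 at 0.60 ± 0.07. The list had adjusted p = 0.0128, and adjusted p = 0.602 with an estimated correlation.

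Ribosome biogenesis genes fell for 61 of 63 (62 adjusted over the list alone), with NOP14 at -0.76 ± 0.07 and SPB1 at -0.70 ± 0.06. The list had adjusted p = 1.39e-23, and adjusted p = 0.389 with an estimated correlation. Oxidative stress genes fell for 16 of 33 and rose for 3 (16 and 4 adjusted over the list alone), including the glutathione synthesis gene GCS1 at -0.76 ± 0.06 and the peroxiredoxin gene PRX1 at -0.90 ± 0.08 (adjusted p = 0.000338, and adjusted p = 0.416 with an estimated correlation). Sulfur assimilation genes fell for 11 of 20 and rose for 1, adjusted over the list alone as well, with MET3 at -0.73 ± 0.06 and CYS3 at -0.73 ± 0.08 (adjusted p = 0.000595, and adjusted p = 0.0797 with an estimated correlation). Electron transport and ATP synthase genes fell for 13 of 31 (14 adjusted over the list alone), with the alternative oxidase gene AOX2 at -0.92 ± 0.07 (adjusted p = 0.00553, and adjusted p = 0.907 with an estimated correlation). Drug efflux genes fell for 14 of 22 and rose for 4, adjusted over the list alone as well, with PDR16 at -0.85 ± 0.07 (adjusted p = 0.047, and adjusted p = 0.602 with an estimated correlation). The drug efflux call ended in the fit of hyphal libraries alone (0.096), and without hyphal control replicate 3 (0.0763), treated hyphal replicates 2 (0.0598) or 3 (0.0766), or treated yeast-form replicates 1 (0.0997) or 2 (0.114).

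Genes that mark the hyphal form moved in both directions in treated hyphae. Of 17 hypha-associated genes 7 rose and 5 fell (8 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.333). The hyphal cyclin gene HGC1 rose by 0.70 ± 0.07, HYR1 by 0.78 ± 0.10, ALS3 by 0.60 ± 0.12, the kinesin gene KIP4 by 0.53 ± 0.13 and HWP1 by 0.46 ± 0.11. ECE1 rose from 3860 ± 162 to 5690 ± 215 CPM (0.56 ± 0.11, adjusted p = 0.000891), although DESeq2 gave an adjusted p of 0.139 (1.3e-06 to 0.139 over the alternatives). ALS1 fell by 0.73 ± 0.11 and SAP6 by 1.23 ± 0.27. SAP5 fell by 0.34 ± 0.10, with an adjusted p of 0.0769 without hyphal control replicate 1 and 0.0515 without treated hyphal replicate 2. RBT1 fell by 0.55 ± 0.17, with an adjusted p of 0.0843 without hyphal control replicate 3, 0.0797 without treated hyphal replicate 2 and 0.0571 without treated hyphal replicate 3. PHR1 fell by 0.23 ± 0.07, with an adjusted p of 0.0505 without treated hyphal replicate 3. IHD1 rose by 0.19 ± 0.07, a call that ended when any single hyphal library was left out, with adjusted p from 0.0647 (without control replicate 3) to 0.208 (without control replicate 2). Among 10 yeast-form genes, SCW11 and NRG1 rose, by 0.89 ± 0.11 and 0.50 ± 0.08, RHD2 fell by 0.40 ± 0.10, and YWP1 stood at 0.80 ± 0.33 with an adjusted p of 0.07. In the fit of the hyphal libraries alone YWP1 stood at 0.78 ± 0.19 with an adjusted p of 0.00317. That fit called 4 of the 10 genes higher and 2 lower.

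In hyphal cultures 2572 genes were called, 1313 higher and 1259 lower, and 60 of them by at least 1 on the log2 scale (41 higher and 19 lower). A fit of the hyphal libraries alone called 3517 (1719 higher and 1798 lower), 2555 of them among the 2572.

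The responses of the growth forms were compared directly by testing their difference, hyphal minus yeast-form. It was called for 2115 genes, 1101 with the higher and 1014 with the lower value in hyphae, and for 210 genes it reached 1 on the log2 scale. The shared fit, at 8.25%, understates the spread of the treated yeast-form libraries, at 13.4%. The simulations did not score this difference, so the share of false calls among the 2115 is not known. Scaling by library size alone gave 1233 and 753. INO1 fell in yeast-form cultures and rose by 0.88 ± 0.10 in hyphae, where its level was low (to 6.25 CPM), a difference of 2.74 ± 0.13. The cyclin gene PCL2, the kinesin gene KIP2, the cohesin subunit gene MCD1 and the transcriptional repressor gene YOX1 fell in yeast-form cultures (-2.02, -2.18, -1.45 and -1.51) and rose in hyphae (0.78, 0.51, 0.86 and 0.97). Their differences were 2.80 ± 0.24, 2.69 ± 0.18, 2.30 ± 0.16 and 2.49 ± 0.30. UCF1 stood at -0.06 in yeast-form cultures against 2.71 in hyphae. The secreted protein gene RBE1 stood at -1.14 against 1.84. FDH1 was lower in both forms, and its difference of 0.06 ± 0.15 did not pass.

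By list, glycolysis and fermentation responded higher in hyphae for 17 of 17 genes (17 adjusted over the list alone; adjusted p = 1.63e-13, and adjusted p = 0.203 with an estimated correlation). Ergosterol and mevalonate genes did so for 15 of 24 (15 adjusted over the list alone; adjusted p = 1.83e-06, and adjusted p = 0.24 with an estimated correlation). So did hexose transport genes for 5 of 13 (5 adjusted over the list alone; adjusted p = 3.23e-05, and adjusted p = 0.203 with an estimated correlation), and trehalose and glycogen genes for 8 of 11 (9 adjusted over the list alone; adjusted p = 0.00915, and adjusted p = 0.702 with an estimated correlation). Amino acid synthesis genes had the higher response in hyphae for 20 of 50 and the lower for 3 (21 and 5 adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.628 with an estimated correlation). Cell cycle and DNA replication genes had the higher response in hyphae for 20 of 38 and the lower for 7 (22 and 8 adjusted over the list alone; adjusted p = 0.000129, and adjusted p = 0.428 with an estimated correlation), with MCM3 at 1.06 ± 0.09 and MCM6 at 1.16 ± 0.12. Yeast-form genes had the higher response in hyphae for 7 of 10 (7 adjusted over the list alone; adjusted p = 0.000311, and adjusted p = 0.203 with an estimated correlation). Ribosome biogenesis genes had the lower response in hyphae for 39 of 63 and the higher for 1 (42 and 1 adjusted over the list alone; adjusted p = 2.46e-10, and adjusted p = 0.628 with an estimated correlation). Oxidative stress genes had the lower response for 12 of 33 and the higher for 5 (14 and 5 adjusted over the list alone; adjusted p = 0.00915, and adjusted p = 0.628 with an estimated correlation), and proteasome genes the lower for 10 of 26 (11 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.793 with an estimated correlation).

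**Figure D4:**
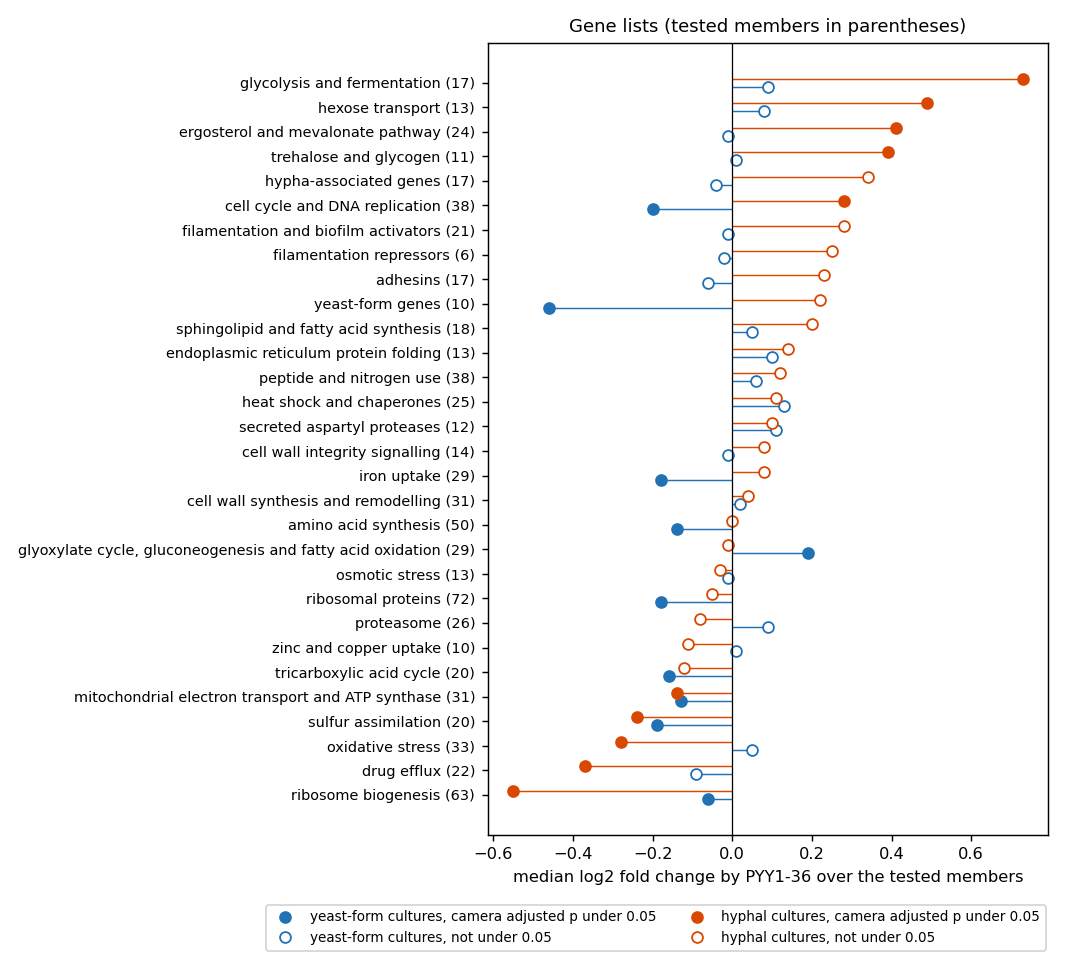
Median log2 fold change by PYY1-36 over the tested members of each fixed gene list in yeast-form (blue) and hyphal (orange) cultures, with filled points where the camera adjusted p at a preset correlation of 0.01 was under 0.05. Glycolysis and fermentation lies highest in hyphae (0.73) and ribosome biogenesis lowest (-0.55), while cell cycle and DNA replication lies at -0.20 in yeast-form cultures and 0.28 in hyphae.

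Genes called in both forms numbered 753, of which 447 changed in the same direction and 306 in opposite directions. These comparisons share no library. Independent lists of the same sizes would share 327 genes in the same direction and 326 in opposite directions. By Fisher's exact test (two-sided, 4 combinations tested), 221 genes rose in both forms against 169 for independent lists (adjusted p = 6.32e-06), and 226 fell in both against 157 (adjusted p = 8.84e-10). The 166 genes that fell in yeast form and rose in hyphae (164 for independent lists) and the 140 that rose and fell (162) did not pass (adjusted p = 0.851 and 0.0503). Genes are not independent replicates, so these 4 p-values do not measure the spread between libraries. Across all tested genes, which are not independent replicates, the log2 fold changes of the forms had a Pearson r of 0.01 and a Spearman rho of 0.04. The same-direction count was 684 without treated yeast-form replicate 1, against 443 for independent lists, and 254 with each form fitted alone, against 193. Without treated yeast-form replicate 2, 400 genes changed in the same direction and 399 in opposite directions, against 350 and 349. The predominance of shared directions was thus absent without that library, whereas without treated yeast-form replicate 1 only 323 genes changed in opposite directions. Which of these 2 replicates is the less typical was not tested.

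**Figure D5:**
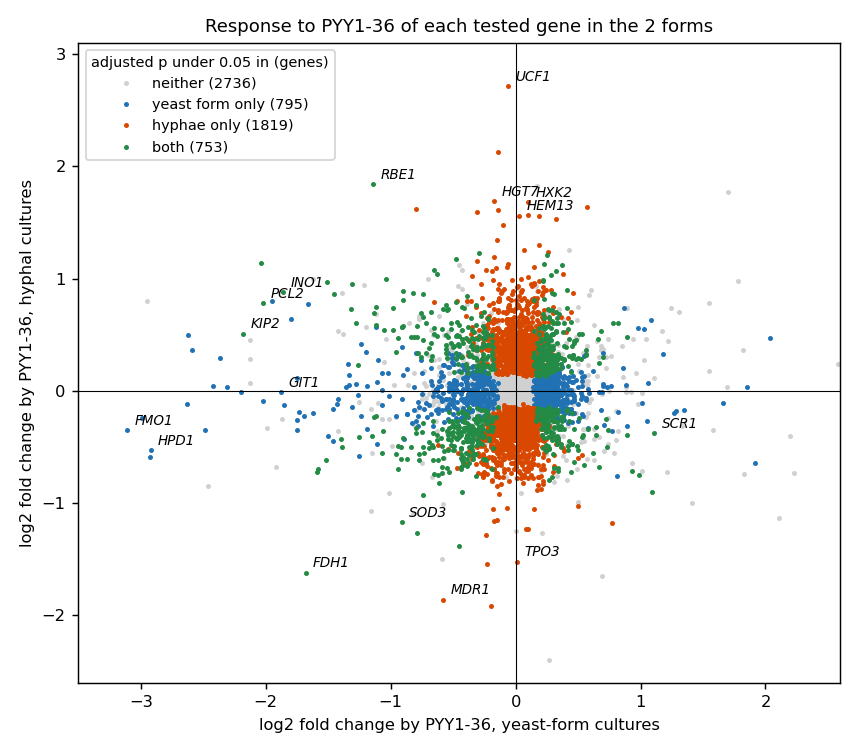
Log2 fold change by PYY1-36 in hyphal cultures against that in yeast-form cultures for each tested gene, coloured by the form in which its adjusted p was under 0.05, with 6 genes outside the axes. The 753 genes called in both forms lie in all 4 quadrants, and FDH1 is low on both axes while UCF1 is high in hyphae only.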

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

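The test for yeast-form cells in the hyphal cultures and the fit without non-coding genes were chosen only after the result was seen. The test of the difference between the responses to PYY1-36 called 2115 genes, with an unknown share of false calls. That count is what brought the results of this part up for a closer look. Among 100 draws that redrew the treatment label within each form, the real labels included, 1 gave as many genes, and the highest of the other draws gave 1855. That was 1 of 11 other draws that kept the treated and control hyphal libraries apart, and the draws that mixed them gave at most 70 genes. Mixing the hyphal labels removes the hyphal response as a whole, so those draws say nothing about a difference between the responses. The real labels and the 11 draws that kept the hyphal libraries apart are too few for a share under 0.05. For the count of 1549 genes in yeast-form cultures, 2572 in hyphal cultures and 5158 between the controls, the 10 possible splits of 6 libraries are too few for a share under 0.05. In each case 1 split, the real one, gave as many genes, and the highest other split gave 0.

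The lists whose response differed were glycolysis and fermentation (adjusted p = 1.63e-13), ribosome biogenesis (2.46e-10), ergosterol and mevalonate pathway (1.83e-06), hexose transport (3.23e-05), cell cycle and DNA replication (0.000129), yeast-form genes (0.000311), oxidative stress (0.00915), trehalose and glycogen (0.00915), proteasome (0.013) and amino acid synthesis (0.0148). With an estimated correlation none of the 30 lists passed, and the smallest adjusted p was 0.203.

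Single genes whose response differed are given as the hyphal minus the yeast-form log2 fold change. Among genes lower in treated yeast-form cultures it was 2.77 for FMO1, 2.74 for INO1, 2.39 for HPD1, 1.93 for PHO100, 1.87 for GIT1, 1.86 for OPT7, 1.49 for PHO112, 0.90 for MET14 and 0.89 for FRE7. The cell cycle genes PCL2, KIP2, YOX1 and MCD1 stood at 2.80, 2.69, 2.49 and 2.30, and RBE1 at 2.98. Among genes higher in treated hyphae it was 2.78 for UCF1, 1.91 for CDR4, 1.85 for HGT7, 1.58 for HXK2, 1.58 for QDR1, 1.53 for HEM13, 1.49 for MAE1, 1.47 for HGT6, 1.36 for PGA10 and 0.96 for OSM1. Among genes lower in treated hyphae it was -1.53 for TPO3, -1.53 for OAC1, -1.33 for OYE32, -1.31 for SAP6, -1.28 for MDR1, -1 for EBP1, -0.93 for IFD6 and -0.87 for GRP2. MDR1 was also lower in treated yeast-form replicates 2 and 3 (9.5 and 8.01 CPM, against 17.6 to 21.9 with saline), but not in replicate 1 (23.3). Genes higher in treated yeast-form cultures gave -2.56 for RDN5, -1.64 for RDN18, -1.52 for RDN58, -1.50 for SCR1, -1.28 for POL93, -1.21 for RDN25, -0.97 for NBP2 and -0.70 for PEX4. CFL11 and FAV1, at 3.18 and -1.93, rest on few counts in yeast-form cultures, where CFL11 had 6, 0 and 2 counts with PYY1-36 and FAV1 had 0, 2 and 11 with saline. The call of RDN58 ended without any single library except treated yeast-form replicates 2 and 3 (adjusted p from 0.0528 without hyphal control replicate 1 to 0.106 without hyphal control replicate 2). By limma-voom RDN58, RDN5 and SAP6 had adjusted p of 0.144, 0.158 and 0.286. SAP6 lost its call without yeast-form control replicates 1 (0.0718) or 2 (0.0675), treated yeast-form replicate 3 (0.107), hyphal control replicates 1 (0.0655) or 3 (0.072) or treated hyphal replicate 3 (0.0618), and FAV1 without yeast-form control replicate 2 (0.0796).

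The first pattern weighed was the fall of 12 of 38 cell cycle and DNA replication genes in treated yeast-form cultures, with a median log2 fold change of -0.66 over these 12, which were taken because they were called lower, while 4 others were called higher and the median over all 38 was -0.20. Leaving out all non-coding genes before scaling left 12 of the 12 called and lower but moved their median by nothing, so it decides nothing, whereas ribosomal RNA took 2.53% of the counts in controls and 4.47% in treated cultures, too little to lower other genes by that much. Leaving out each of the 6 yeast-form libraries kept their median at -0.54 or below, with 10 to 12 of them still called. The 12 had been taken because they were called lower with all libraries, so that check decides little. By camera the call of the whole list ended without yeast-form control replicate 3 (adjusted p = 0.0766) or treated yeast-form replicate 1 (0.086). After the trend of fold change on gene length was subtracted (Spearman rho across genes -0.17) the median of the 12 was -0.63. A response of these 12 genes in yeast-form cells to PYY1-36 remains as a hypothesis, and neither growth rate nor culture density was among the data used here.

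The second pattern was the rise of 27 of the 30 tested genes of glycolysis and hexose transport in treated hyphae, with a median log2 fold change of 0.72. Of the 30 genes, 17 of 17 in glycolysis and 11 of 13 in hexose transport were more abundant in yeast-form controls, so a larger share of such cells in the treated hyphal cultures could raise most of them, and the 24 of the 27 with a yeast-form level over 2 times the hyphal level imply a median share of 18.9%. At that share, 100 other abundant genes with the largest yeast-form excess would have risen by a median of 1.84, but their median was 0.34 (quartiles 0.04 and 0.59), and 1 of the 100 reached the level its share needs. These values argue against a share of 18.9% of cells with the yeast-form control profile. The reckoning takes that profile for the admixed cells, which would raise each of the 24 genes. The lowest share that any of them implies, 0.0877%, is therefore the most it allows if no other change lowered that gene. It comes from HGT17 alone, at 0.58 CPM in hyphal controls, 0.956 in treated hyphae and 429 in yeast-form controls. Such a share would raise the 100 genes by a median of 0.02. With scaling factors taken from the other genes, 27 of the 27 were still called and higher. Their median moved only from 0.72 to 0.69, and they had been taken because they were called higher, so that check decides little. After subtraction of the trend on gene length (rho 0.22) the median of the 27 was 0.70. A response of hyphae to PYY1-36 remains as a hypothesis.

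The third pattern was the rise of 6 ribosomal and other non-coding RNAs in treated yeast-form cultures, at a median log2 fold change of 1.02. If selection of polyadenylated RNA had been less complete in those libraries, other RNAs without a poly(A) tail would rise too. The median of 69 small nucleolar RNAs was 0.38 and 52 of them were above 0, which goes with that technical explanation. The rise was uneven, with medians of 1.08 for 5 small nuclear RNAs and 0.24 for 29 tRNAs. Across treated libraries the shares of counts did not rise together. Replicate 2 had 5.805% ribosomal and 0.226% small nucleolar RNA, and replicate 1 had 4.382% and 0.323%. The technical explanation is thus not settled. Leaving out single yeast-form libraries kept the median of the 6 RNAs at 0.82 or above, although RDN18 and RDN58 lost their calls in some of these fits. The 6 had been taken from the largest called increases over all libraries, so that check decides little. A change of these RNAs within the cells stays open and was not tested.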

How the results depend on the processing

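Under RLE scaling, library size alone, DESeq2, limma-voom, no filter, a filter at a mean of 10 CPM and, added after the data had been seen, protein-coding genes alone, each of the 4 counts of genes and the same-direction count stayed within 1.5 times its value. The fit of the groups compared alone gave 658 genes in yeast-form cultures in place of 1549 and 254 in the same direction in place of 447, but 3517 in hyphal cultures in place of 2572. It used the spread of each form's own libraries, which for the yeast form is larger than that of all 12. Requiring at least 1 on the log2 scale, which removes small changes, left 95 genes in yeast-form cultures, 60 in hyphae, 210 for the difference of the responses and 2337 between the controls. The difference of responses from separate fits of each form, also added afterwards, called 2473 genes, 2103 of them among the 2115, by a normal approximation that is too generous for so few libraries. Leaving out each library in turn gave 1060 to 1785 genes in yeast-form cultures, 2064 to 3046 in hyphae, 1661 to 2473 for the difference, 4950 to 5301 between the controls and 307 to 684 in the same direction. The correlation across genes of 0.01 went to -0.08 without a filter and 0.05 with the stricter filter, and lay between -0.04 and 0.09 without single libraries, and the cause was not tested. ALS1 between the controls went from -0.02 to 0.62 under library size alone, whose construction shifts the median gene. With replicate number as a block, 1304 genes were called in yeast-form cultures, 2411 in hyphae, 1896 for the difference, 5079 between the controls and 369 in the same direction. The deviations of same-numbered libraries correlated between -0.18 and 0.04, so no shared deviation by replicate number was seen. A small one could be hidden by the spread between libraries, so whether the numbers pair the samples stays unknown. Of the 45 list calls at the preset correlation, 2 held with an estimated correlation. At this depth replicate spread, with a variance 7.9 to 44.1 times that of counting for the median gene, sets the precision.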

Other observations

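The comparison of the responses with the difference between the forms was chosen only after the result was seen, and so were the 3 added lists described first. Genes of phosphate acquisition fell in treated yeast-form cultures for 10 of 17 tested members and rose for 1, with the phosphate transporter gene PHO84 at -1.39 ± 0.10 (SE), the acid phosphatase gene PHO113 at -1.42 ± 0.09 and GIT4 at -2.42 ± 0.26. In treated hyphae 3 rose and 2 fell, PHO84 among the latter at -0.50 ± 0.09. Of 17 genes of late G1 and sister chromatid cohesion, 8 fell and 2 rose in treated yeast-form cultures, while in hyphae 13 rose and none fell, including the mismatch repair gene MSH6 at 0.76 ± 0.07. Of 7 heme synthesis genes in hyphae, HEM13 and HEM14 rose, by 1.56 ± 0.08 and 0.70 ± 0.07, and HEM3 and HEM1 fell, by 0.29 ± 0.07 and 0.23 ± 0.07. Since some members of each list had been seen to change, these counts are no independent evidence.

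Single genes among the regulators and cell surface genes also changed. The lists of filamentation activators, filamentation repressors, adhesins and cell wall synthesis did not pass in treated yeast-form cultures or treated hyphae. Of 31 genes of cell wall synthesis and remodelling, the fit of the yeast-form libraries alone called 2 higher and 4 lower. The fit of the hyphal libraries alone called 9 higher and 7 lower. In treated yeast-form cultures the transcription factor genes EFG1 and ROB1, known as activators of filamentation and biofilm growth, fell by 0.96 ± 0.14 and 0.68 ± 0.12, whereas the activator gene CZF1 rose by 0.29 ± 0.07. Of 21 activators 2 rose and 4 fell, adjusted over the list alone as well (adjusted p = 0.592). Of 6 repressors TUP1 rose by 0.33 ± 0.05 and NRG1 fell by 0.47 ± 0.08 (adjusted p = 0.961). The chitinase genes CHT2 and CHT3 fell by 1.28 ± 0.10 and 1.12 ± 0.15, and the chaperone gene SSA2 fell by 1.28 ± 0.07 there and rose by 0.60 ± 0.07 in hyphae. Of 25 heat shock and chaperone genes in treated hyphae 10 rose and 6 fell (11 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.333). The genes that rose included HSP70, HSP104 and HSP90, by 0.98 ± 0.08, 0.79 ± 0.08 and 0.72 ± 0.08, and those that fell included MDJ1, by 0.40 ± 0.07 (named after its value was seen). Elsewhere in treated hyphae the wall glucanosyltransferase gene PGA4 rose by 0.70 ± 0.05 and PCK1 by 1.08 ± 0.09, while the citrate synthase gene CIT1 fell by 0.53 ± 0.05 and the siderophore transporter gene SIT1 by 0.74 ± 0.09.

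One hypothesis was that treated hyphae moved towards the profile of the yeast form. Across 6103 genes the hyphal response had a covariance of -0.179 (log2 units) with the hyphae-minus-yeast difference (Pearson r -0.36, Spearman rho -0.36). The comparisons share the hyphal controls, and 50 simulations of treated hyphae without any response gave a mean covariance of -0.00411, with a range from -0.00891 to 0.000316, so the shared controls alone do not give this value, and the difference of -0.175 estimates the rest. Which gene groups carry it was not tested. Hypha-associated genes went both ways, since 7 rose, and thus moved away from the yeast-form level, and 5 fell, among them ALS1, which did not pass between the controls. The yeast-form response also ran against the same difference, with a covariance of -0.11 (r -0.22, rho -0.36), where 50 simulations with the shared yeast-form controls gave a mean of 0.0158 and a range from 0.009 to 0.0235. In yeast-form cultures this may mean a move away from the hyphal profile, although the yeast-form list itself fell there. Of its fallen members, SCW11, NRG1, ALS4 and RHD3 were lower in hyphal than in yeast-form controls. RHD1 (-1.46) and RHD2 (-1.15) were higher in hyphal controls, so their fall goes with such a move. Genes are not independent replicates.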
